A study of Mus musculus with 6 samples.

How the data were processed

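Single-cell suspensions of 12 mouse tumours, 3 per treatment group, were measured in 2 pooled droplet libraries, with a hashtag antibody count per tumour. Per the labels' protocols, tumours were taken apart with a dissociation kit and leukocytes were taken from a Percoll gradient. The first library pooled the standard diet and butanediol tumours, the second the checkpoint blockade and combined tumours. Per the labels, the butanediol food held 80 mL of 1,3-butanediol, 120 mL of water, 198 g of chow and 2 g of saccharine.

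The deposited gene matrices hold UMI counts per gene and barcode, made with Cell Ranger 6.1.1 per the file headers. The submitters' processing notes name Cell Ranger, R 4.1 and the mm10 build. The deposited hashtag matrices hold counts per barcode and sequencing lane, and their counting tool and whether reads or UMIs were counted are not given in the sources used here. The deposited table of cells gives a class, a tumour and the percent of mitochondrial UMIs for each cell, and the settings of clustering and naming are not given in the sources used here. The deposited expression table holds counts for 18848 of the 32287 genes, equal to the matrices in all cells, and 0.00369% of counts lay outside it. No genome was used, so no coordinates are given.

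Of 36632 barcodes, 5749 (15.7%) were in the deposited table. These were the barcodes with a hashtag total above 500, under 5% mitochondrial UMIs and at least 250 genes, each assigned to its top hashtag, as tested on the files. The deposited classes and assignments were used as they stand. No doublet caller was run. Droplets with cells of 2 tumours were addressed by a stricter hashtag rule (top hashtag at least 10 counts and 3 times the second, 5325 cells), whereas doublets within a tumour remain. Between the libraries 1931 barcodes were shared, with 42.2 expected by chance. Of these, 1866 had UMI totals over 20-fold apart, and 1 deposited cell was such a shallower copy. Median UMIs per cell ranged from 4545 to 10817 over the tumours.

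The tumour was the replicate. Shares of cells per tumour were compared by two-sided exact permutation of tumour labels, within each library and with diet labels permuted within both, adjusted over 19 classes by the Benjamini-Hochberg method. For genes, counts were summed per tumour and class with at least 10 cells, and fitted with edgeR's quasi-likelihood test (TMM, filterByExpr, robust) on 4 treatment groups, in classes with 2 or more tumours in each group compared. Adjusted p-values are Benjamini-Hochberg values at a threshold of 0.05 over the genes of a class. Levels are CPM, the summed counts scaled to the library size. The labels name 3 different tumours per group but no mice; where tumours shared a mouse, p-values measure only the spread between these tumours.

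There were 27 gene lists, fixed before the data were examined together with the groups, tests, the alternatives to be tried and the rule for named genes. Lists with at least 5 tested genes entered camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. The lists on immunity covered MHC class I and class II presentation, interferon-gamma and type I interferon responses, classically and alternatively activated macrophages, suppressive granulocytes, immature neutrophil granules, chemokines and receptors, and the inflammasome. Lists on T cells covered exhaustion, cytotoxic effectors, naive and memory cells and regulatory cells. Lists on metabolism and regulation covered ketone body use, histone deacetylases, genes raised by deacetylase inhibitors, glycolysis, hypoxia, fatty acid oxidation, oxidative phosphorylation and proliferation. The remaining lists held the NF-kB and TNF response, dissociation, and red cell, prostate epithelium and fibroblast genes. Named genes were, per class and contrast, up to 5 raised and 5 lowered with the smallest adjusted p, taken by cell number of the class to about 30 per comparison, up to 4 members of each list, and a fixed set of immune genes. The result of 1 gene that this rule takes up is not reported here.

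Alternatives were DESeq2, RLE size factors, no filter on low counts, at least 30 cells per tumour, cells with at least 1000 UMIs, the stricter hashtag rule, own demultiplexing, the replicate number as a block, the deposited expression table, only the tumours of the library, edgeR on cells per class, shares without neutrophils or of immune classes, and leaving out each tumour. Where the latter left 1 tumour in an arm, it was assumed to vary like the other groups. Own demultiplexing used the top hashtag at 10 or more counts and 3 times the second with no limit of 500, and classes were carried over from deposited cells by 15 nearest neighbours on 30 principal components of 2000 genes; in deposited cells this gave the deposited class in 80.8%, but in 34.0% for Nos2+ dendritic cells, 23.5% for other macrophages and 57.3% for Ifit+ neutrophils. Merged compartments were added after the class results were seen. Own Leiden clusters (resolution 1) served only to check classes and the makeup of the proliferating immune cells. The leading genes of a class were its 10 highest by fold of CPM over the mean of the other classes (pseudocount 20, at least 100 CPM), a check chosen after the results were seen.

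Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and leidenalg 0.10.2. The gene test was tested on simulated data with 200 changed genes. For Trem2+ macrophages, BD against SD (5049 genes), it recovered 41% of 2-fold and 89% of 4-fold changes with 11 false calls. For CD8 T cells, BD+ICB against ICB (5375 genes), these were 52% and 93% with 5 false calls, and for M1 macrophages (6701 genes) 78% and 98% with 6. The share test gave a p under 0.05, without adjustment over classes, in 3% of 200 simulations without a difference. With a 3-fold lower share it did so in 87.5%. These values do not give the power of the test adjusted over the classes, which was not simulated. They rest on a common share and spread, not on those of each class, and on a drop in both libraries.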

Results

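Tumours of PPS-ICBR, a mouse prostate cancer cell line resistant to immune checkpoint blockade, were taken from C57Bl6 mice and profiled by droplet-based single-cell RNA sequencing. The 4 treatment groups held 3 tumours each. Mice received a standard diet (SD), a butanediol diet (BD), immune checkpoint blockade directed at PD-1 and CTLA-4 with a listed dose of 0.2 mg (ICB), or the butanediol diet together with the blockade (BD+ICB). The butanediol diet was chow mixed with 1,3-butanediol, which the body converts to the ketone body β-hydroxybutyrate. The question named by the series was whether a ketone-raising diet changes resistance of prostate tumours to immunotherapy.

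Cells of each tumour carried their own hashtag. The SD and BD tumours shared 1 library and the ICB and BD+ICB tumours another, so each diet comparison lay within a library, whereas the blockade and the library could not be told apart. The tumour was the replicate. The deposited annotation held 5749 cells in 19 classes, 1215 in SD, 490 in BD, 2314 in ICB and 1730 in BD+ICB. Cells per tumour ranged from 70 in BD replicate 2 to 913 in ICB replicate 3. Total UMI counts per tumour ranged from 510992 in BD replicate 2 to 13008109 in ICB replicate 1. The listed tumour sizes, whose unit was not stated, were 1478 ± 773 in SD, 184 ± 16.4 in BD, 800.0 ± 447 in ICB and 53.7 ± 33.9 in BD+ICB (SD, n = 3), without overlap between the diets in either library. Diet was therefore tied to tumour size as well as to the hashtag set, since hashtags 3 to 5 marked the tumours on standard chow and hashtags 6 to 8 those on butanediol.

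The first comparison asked how the diet related to the cellular makeup of the tumours, measured in the leukocyte layer of a Percoll gradient, so that shares are those of this fraction. Mesenchymal cells made up 12.2% ± 1.64 of cells in SD and 2.12% ± 1.10 in BD tumours, and 3.20% ± 1.37 in ICB and 0.920% ± 0.494 in BD+ICB tumours (SD, n = 3). Proliferating cancer cells stood at 3.35% ± 0.921 in SD, 0.220% ± 0.381 in BD, 3.00% ± 1.24 in ICB and 1.66% ± 0.461 in BD+ICB. The macrophage class named M1 by the authors stood at 2.47% ± 1.24 in SD, 9.42% ± 7.07 in BD, 6.37% ± 0.750 in ICB and 17.1% ± 1.33 in BD+ICB. The deposited name was kept. The 10 leading genes of this class held Arg1 and Msr1 of the alternatively activated macrophage list and none of the classically activated list. The Mmp+ M2 macrophages stood at 4.26% ± 1.04 in SD and 15.5% ± 0.847 in BD, but at 6.64% ± 1.44 in ICB and 7.02% ± 3.21 in BD+ICB. CD8 T cells stood at 2.61% ± 0.289 in SD, 1.28% ± 1.53 in BD, 9.40% ± 4.59 in ICB and 16.9% ± 7.41 in BD+ICB. Every deposited cell had over 500 hashtag counts. Own demultiplexing had no such limit but required the top hashtag to be 3 times the second. With it, mesenchymal cells made up 48.7% ± 6.84 in SD, 23.2% ± 5.55 in BD, 12.2% ± 4.57 in ICB and 5.86% ± 3.60 in BD+ICB. Proliferating cancer cells made up 9.17% ± 2.68, 6.18% ± 3.01, 9.75% ± 4.63 and 8.20% ± 4.36 in the same order. M1 macrophages then stood at 1.01% ± 0.400 in SD, 4.16% ± 3.13 in BD, 5.10% ± 1.34 in ICB and 13.4% ± 1.03 in BD+ICB, and Mmp+ M2 macrophages at 2.25% ± 1.63, 7.44% ± 1.17, 5.21% ± 1.63 and 5.44% ± 2.39. Of immune cells, the Mmp+ class made up 5.00% in SD and 10.7% in BD, with SD replicate 2 (8.04%) above BD replicate 2 (7.75%). For CD8 T cells the direction between SD and BD then turned, at 1.24% ± 0.200 and 2.10% ± 1.66, which rested on BD replicate 1 (BD 1.14% without it), and ICB and BD+ICB stood at 6.86% ± 2.40 and 14.7% ± 7.13. Of immune cells, CD8 T cells made up 2.96% in SD and 3.14% in BD, or 1.55% without BD replicate 1.

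None of the 19 classes passed the test of the diet effect over both libraries, a two-sided exact permutation of diet labels within each library. The effect on mesenchymal cells was -6.16 percentage points (p = 0.005, the smallest the permutation can give, adjusted p = 0.095). Adjusted over the 19 classes, a lone class at that smallest p cannot pass. The lack of a call therefore does not exclude a change in a class. The other effects with an exact permutation p under 0.05 were -2.24 points for proliferating cancer cells (p = 0.01, adjusted p = 0.095), -1.68 for Ifit+ neutrophils (p = 0.015, adjusted p = 0.095), 8.84 for M1 macrophages (p = 0.02, adjusted p = 0.095) and -11.0 for Cxcr2+ neutrophils (p = 0.04, adjusted p = 0.136). With own demultiplexing these effects were -15.9 points for mesenchymal cells (adjusted p = 0.19), -2.27 for proliferating cancer cells (0.459), -0.712 for Ifit+ neutrophils (0.232) and 5.72 for M1 macrophages (0.19), by the same exact permutation. For Cxcr2+ neutrophils the effect was then -1.80 points (exact permutation, adjusted p = 0.755), with 9.98% ± 3.88 in SD, 13.9% ± 11.9 in BD, 13.2% ± 8.66 in ICB and 5.65% ± 3.94 in BD+ICB. CD8 T cells differed by 3.10 points (exact permutation p = 0.35, adjusted p = 0.475). Within either library, an exact permutation of 3 tumours against 3 cannot go below p = 0.1, and no class passed. Every BD tumour lay below every SD tumour for mesenchymal cells, and every BD+ICB tumour below every ICB tumour. Within either library taken alone, chance gives such a separation in 10% of arrangements of 3 against 3. Both libraries together gave the exact permutation p of 0.005 above. The diet effects did not differ detectably between the libraries, with the smallest interaction p at 0.045 for Ifit+ monocytes (1.02 points, exact permutation, adjusted p = 0.348). Testing cells per class with edgeR instead gave 7 classes for the diet effect, including mesenchymal cells (log2 fold -2.12, adjusted p = 0.00301), Hilpda+ neutrophils (log2 fold -1.97, adjusted p = 0.00301) and the class named Nos2+ dendritic cells (log2 fold 2.08, adjusted p = 0.00301). Between BD+ICB and ICB it called Hilpda+ neutrophils (log2 fold -3.36, adjusted p = 9.8e-04) and Nos2+ dendritic cells (2.26, adjusted p = 0.0157). In the Nos2+ class 12 of 12 macrophage markers and 9 of 12 monocyte markers lay over 20 CPM, against 3 of 8 for type 1, 1 of 9 for type 2 and 1 of 9 for migratory dendritic cells. Without BD replicate 2, and likewise without ICB replicate 3, 2 classes passed the permutation test.

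**Figure D1:**
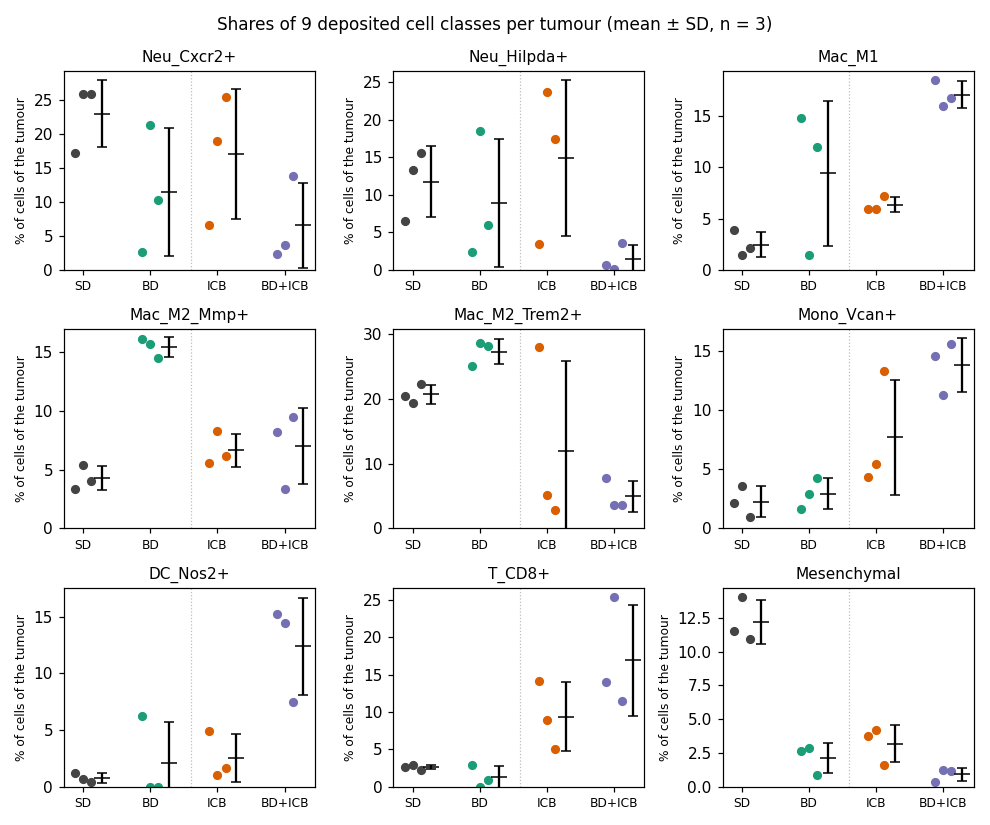
Share of the cells of each tumour, in percent, for 9 deposited classes; points are tumours, the horizontal mark is the mean and the bar is the SD (n = 3, truncated at 0), with the library boundary dotted. Mesenchymal cells averaged 12.2% in SD and 2.12% in BD tumours, and M1 macrophages 6.37% in ICB and 17.1% in BD+ICB tumours.

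The limit of 500 hashtag counts kept unequal parts of the compartments and groups. Among droplets assigned without it, mesenchymal cells lay above 500 in 1.49% to 3.33% of BD and 6.15% to 15.4% of SD cells, and proliferating cancer cells in 0% to 2.70% and 11.3% to 17.8%. For T cells this was 33.3% to 60% in BD and 81.2% to 100% in SD tumours, and for macrophages 65.4% to 68.8% and 55.1% to 75.4%. The median hashtag count per neutrophil was 402 to 494 in the 3 BD tumours and 1429.5 to 1575 in the 3 SD tumours. The share of neutrophils above that limit was 22.7% to 48.4% in BD and 91.7% to 94.6% in SD tumours. In BD+ICB replicates 1, 2 and 3 the neutrophil medians were 480.5, 606 and 946, with 47.4%, 69.2% and 93.1% above the limit, against 98.2% to 99.2% in ICB tumours. Own demultiplexing lifts the limit but also requires the top hashtag to be 3 times the second, so its shares reflect both. Of deposited cells, this stricter rule left out 9.79% of Cxcr2+, 15.2% of Hilpda+ and 20% of Ifit+ neutrophils. It left out 18.7% of mesenchymal cells and 3.57% of Trem2+ macrophages. Without the limit and with this rule, neutrophils made up 15.0% ± 6.09 of SD and 22.3% ± 20.9 of BD cells. The difference was 7.35 points, in the other direction than among deposited cells (exact permutation p = 0.8). It was -4.68 points without BD replicate 2, where neutrophils made up 46.4% of cells. Of immune cells, neutrophils without the limit made up 34.7% in SD and 29.8% in BD, a difference of -4.89 points (exact permutation p = 0.8) against -21.7 among deposited cells, and -19.2 against -31.9 without BD replicate 2. It was 3.27 against -13.8 without BD replicate 1 and 1.28 against -19.5 without BD replicate 3. Between BD+ICB and ICB the difference without the limit was -18.3 points (exact permutation p = 0.2), against -26.05 among deposited cells.

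**Figure D2:**
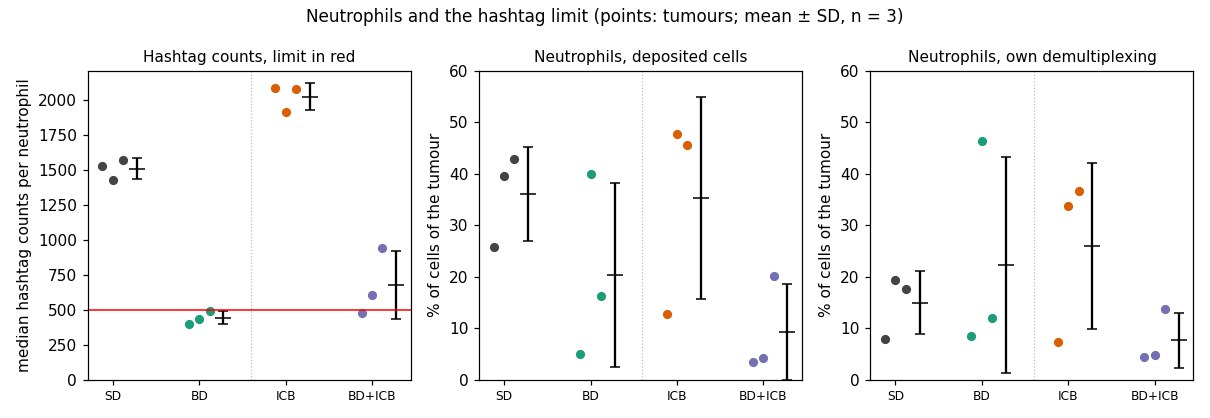
Left, median hashtag counts per neutrophil and tumour with the limit of 500 as a red line; middle and right, neutrophils in percent of the cells of each tumour among deposited cells and after own demultiplexing without the limit (points, tumours; mark and bar, mean ± SD, n = 3, truncated at 0). The 3 BD tumours lie at 402 to 494 counts, under the limit.

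Merging the 19 classes into 9 compartments was added after the class results had been seen, and adjusts over fewer tests. With unchanged shares and exact permutation p-values, the adjusted p of the mesenchymal and of the proliferating cancer cells then became 0.045. Both calls ended without BD+ICB replicate 2 or BD+ICB replicate 3 (adjusted p = 0.0675), and with own demultiplexing (adjusted p = 0.09 and 0.36). Merged neutrophils stood at 36.0% ± 9.07 in SD and 20.4% ± 17.9 in BD, and at 35.4% ± 19.6 in ICB and 9.29% ± 9.35 in BD+ICB (diet effect -20.8 points, exact permutation p = 0.045, adjusted p = 0.09). Merged macrophages gave a diet effect of 13.8 points (p = 0.05), dendritic cells, of which the Nos2+ class held 219 of 265 in BD+ICB and 9 of 39 in SD tumours, of 6.86 (p = 0.04) and T cells of 5.24 (p = 0.175), all by the same exact permutation test and none past adjustment. Left-out tumours brought neutrophils to -25.7 (without BD replicate 2) and -26.5 points (without ICB replicate 1), macrophages to 17.1 (without ICB replicate 1) and dendritic cells to 8.45 (without BD replicate 2), each then past adjustment. The effect on T cells was 2.35 points without BD+ICB replicate 2 and 7.27 without BD+ICB replicate 3. With own demultiplexing and immune classes only, a setting added after the results were seen, the macrophage effect was -0.643 points, with 46.9% in SD, 49.8% in BD, 38.9% in ICB and 34.7% in BD+ICB.

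The next comparison asked which genes differed between BD and SD tumours within a cell class. In M1 macrophages, Ptgs2 (ENSMUSG00000032487), the inducible cyclooxygenase of prostaglandin synthesis, rose from 220 ± 62.5 to 1056 ± 395 CPM, the counts scaled to library size, (SD, n = 2 tumours each), a log2 fold change of 2.26 ± 0.31 (SE, edgeR adjusted p = 0.0138). Ifitm3, an interferon-induced membrane protein, fell in the same cells (-1.06 ± 0.18, adjusted p = 0.0138), as did Cd300c2 (-1.14 ± 0.22) and Rrbp1 (-1.04 ± 0.20, both adjusted p = 0.0416). In Mmp+ M2 macrophages, Fabp5 (ENSMUSG00000027533), a fatty acid binding protein, rose from 497 ± 116 to 1477 ± 189 CPM (SD, n = 3; log2 fold 1.58 ± 0.22, edgeR adjusted p = 8.6e-04). In Cxcr2+ neutrophils, Hcar2 (ENSMUSG00000045502), the cell surface receptor for β-hydroxybutyrate, went from 973 ± 165 (n = 3) to 249 ± 128 (n = 2) CPM (log2 fold -1.90 ± 0.37, edgeR adjusted p = 0.0403).

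These 6 genes were all that passed with edgeR in the 4 classes that could be tested, where DESeq2 called 31. The number was 0 with at least 30 cells per tumour, 23 without BD replicate 1, 12 without SD replicate 3, 2 without ICB replicate 2 or BD+ICB replicate 1, and 3 without SD replicate 1, ICB replicate 3, BD+ICB replicate 2 or BD+ICB replicate 3. With at least 30 cells per tumour, only Trem2+ macrophages could still be tested, so the 0 of that setting says nothing on the 6 genes. Trem2+ M2 macrophages gave 0 genes with edgeR, 314 at an unadjusted p under 0.05 and 0 with DESeq2. The type I interferon list lay lower in BD tumours in 2 of the 3 macrophage classes tested, and not in Trem2+ macrophages (median 0.14, camera direction down, adjusted p = 0.71), a difference between classes that was not tested. The interferon-gamma list was not called in any of the 3 (smallest camera adjusted p = 0.0843). For the type I interferon response, 14 of 15 tested genes had negative folds in Mmp+ macrophages (median -0.91, camera adjusted p = 1.2e-09, adjusted p = 0.313 with an estimated correlation), where 0 genes passed over all genes and 1 fell when adjusted over the list alone. The dissociation and immediate early list was also called lower in Mmp+ macrophages (median -0.20, camera adjusted p = 0.0415, adjusted p = 0.528 with an estimated correlation), with 0 of 19 genes past either adjustment. In M1 macrophages the type I interferon list had a median of -1.31 over 13 genes (camera adjusted p = 4.3e-06, adjusted p = 0.581 with an estimated correlation), with 0 genes over all and 2 lower adjusted over the list alone. MHC class II presentation had a median of -0.62 over 9 genes in M1 macrophages (camera adjusted p = 1.1e-04, adjusted p = 0.581 with an estimated correlation), with 0 genes over all and 2 lower adjusted over the list alone. MHC class I presentation was also called lower there by camera, but not with an estimated correlation. Its direction turned without SD replicate 1, which left 1 SD tumour. In Cxcr2+ neutrophils, the NF-kB and TNF early response list was higher, with 15 of 19 folds positive (median 0.35, camera adjusted p = 9.9e-07, adjusted p = 0.383 with an estimated correlation) and 0 genes past either adjustment. The call for Hcar2 ended without each of the 11 tumours of its fit (highest adjusted p = 0.519), which BD replicate 1 with 8 such cells did not enter. It also ended with DESeq2, RLE size factors, the replicate block, the stricter hashtag rule and only the tumours of the library (adjusted p = 0.0829 to 0.321). Its fold was 0.055 with own demultiplexing (adjusted p = 0.992). The runs without BD replicate 2 or 3 left it 1 BD tumour. In M1 macrophages, with 2 SD and 2 BD tumours in the fit, a run without 1 of these compares an arm of 1 tumour, assumed to vary like the other groups. In these cells, the calls for Ptgs2, Ifitm3, Cd300c2 and Rrbp1 all ended with only the tumours of the library. Those for Ptgs2, Cd300c2 and Rrbp1 also ended with the replicate block, and those for Ifitm3 and Rrbp1 with own demultiplexing. The call for Ptgs2 ended without SD replicate 1 (adjusted p = 0.141) or without ICB replicate 2 (0.0604), and that for Fabp5 ended with own demultiplexing (1.22, adjusted p = 0.091). Ifitm3, Cd300c2 and Rrbp1 lost their calls without SD replicate 1 (adjusted p = 0.213, 0.141 and 0.448), BD replicate 1 (0.0561 each), BD replicate 3 (0.0944, 0.202 and 0.213) or BD+ICB replicate 1 (0.101, 0.119 and 0.119). Cd300c2 and Rrbp1 also lost theirs without any 1 of the other ICB and BD+ICB tumours (0.0517 to 0.0945), and Cd300c2 without SD replicate 3 (0.119).

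Under checkpoint blockade, the diet comparison gave 203 genes in the 13 classes that could be tested, 79 raised and 124 lowered in BD+ICB over ICB. The total was 108 without ICB replicate 2, 130 without BD+ICB replicate 2 and 352 without BD+ICB replicate 3. Proliferating cancer cells accounted for 101, with 45 raised and 56 lowered. This fit rested on few cells, 12 and 11 in BD+ICB replicates 1 and 2 against 36, 16 and 17 in the ICB tumours. BD+ICB replicate 3, with 6 such cells, did not enter it. Among the raised genes were parts of MHC class I antigen presentation. H2-K1 (ENSMUSG00000061232), a classical MHC class I heavy chain, rose from 807 ± 48.6 (n = 3) to 1427 ± 80.2 (n = 2) CPM (log2 fold 0.82 ± 0.10, edgeR adjusted p = 9.0e-04). Tap1 (1.26 ± 0.17, adjusted p = 0.00363) and Tap2 (1.00 ± 0.19, adjusted p = 0.0186), which form the peptide transporter, also rose, as did H2-D1 (0.59 ± 0.10) and B2m (0.52 ± 0.10), the light chain. Of the 18 genes of that list, 7 rose over all genes and 12 when adjusted over the list alone, with none lower (median 0.81, camera adjusted p = 6.3e-21, adjusted p = 0.143 with an estimated correlation).

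All 17 tested genes of the interferon-gamma response had positive folds in the proliferating cancer cells (median 1.46, camera adjusted p = 4.8e-24, adjusted p = 0.143 with an estimated correlation), 3 past adjustment over all genes and 13 adjusted over the list alone. These included the GTPases Irgm1 (1.20 ± 0.18, edgeR adjusted p = 0.00434) and Gbp5 (1.63 ± 0.29, adjusted p = 0.0167) and the transcription factor Irf1 (0.61 ± 0.12, adjusted p = 0.0272). The chemokine gene Cxcl9 had a fold of 2.30 ± 0.31 but an adjusted p of 0.0529. The nuclear receptors Nr4a2 (-1.72 ± 0.17, edgeR adjusted p = 2.3e-04) and Nr4a1 (-0.87 ± 0.16, adjusted p = 0.023) fell. They belonged to the T-cell exhaustion and checkpoint list, of which 5 genes were tested and 2 fell under either adjustment (camera adjusted p = 6.6e-07, adjusted p = 0.143 with an estimated correlation). Markers of macrophages, monocytes, T cells and neutrophils in these cells had median folds of -1.56, -0.51, -1.87 (1 gene) and -2.11. The count of 101 was 35 without ICB replicate 2 and 48 without BD+ICB replicate 1. Runs without BD+ICB replicate 1 or 2 left 1 BD+ICB tumour, assumed to vary like the other groups. Without ICB replicate 2 and without BD+ICB replicate 1, in that order, the calls for H2-D1 (adjusted p = 0.0661 and 0.119), Tap2 (0.0751 and 0.155), Gbp5 (0.0761 and 0.248), Irf1 (0.136 and 0.255) and Nr4a1 (0.0591 and 0.192) ended. Without ICB replicate 1, the calls for Tap2 (0.0609), Irf1 (0.0786) and Nr4a1 (0.0786) ended. Calls also ended without ICB replicate 3 for Irf1 (0.0506) and Nr4a1 (0.0557), and without BD+ICB replicate 2 for Nr4a1 (0.0751). The fold of H2-K1 was 1.21 with own demultiplexing, where its call ended (adjusted p = 0.325). The calls for H2-D1, Tap1, Tap2, Irgm1, Gbp5, Irf1 and Nr4a1 ended in that setting too. Nr4a2 was not among the calls that ended. Of the proliferating cancer cells in that setting, 6.38% to 29.4% in BD+ICB and 17.6% to 23.6% in ICB tumours lay over the limit of 500 hashtag counts.

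**Figure D3:**
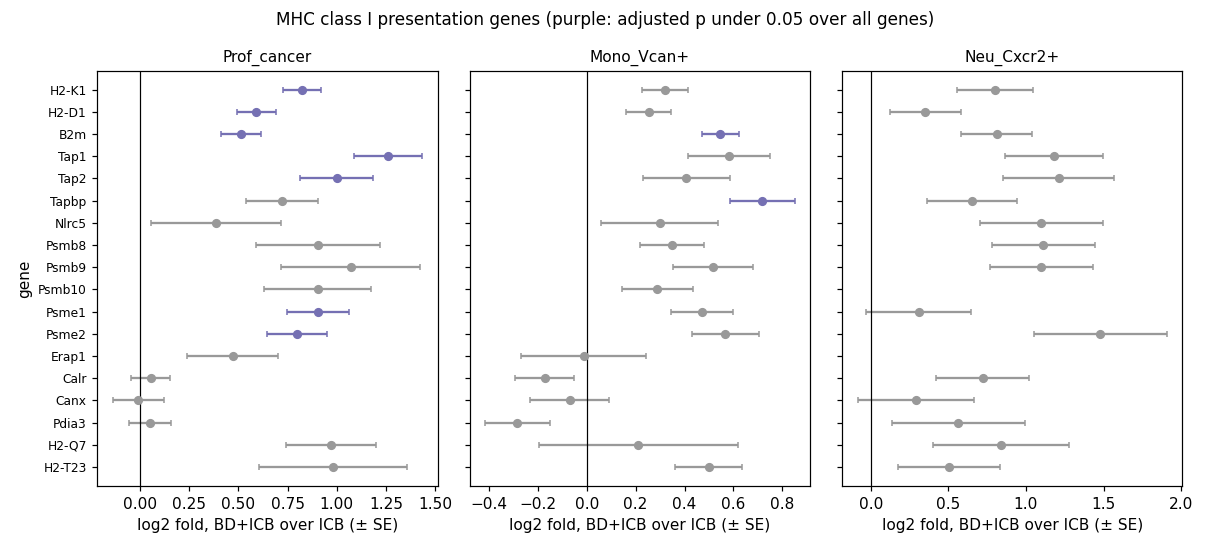
Log2 fold change of BD+ICB over ICB (x axis) with its SE for the 18 genes of the MHC class I presentation list (y axis) in proliferating cancer cells, Vcan+ monocytes and Cxcr2+ neutrophils; purple marks an edgeR adjusted p under 0.05 over all genes, and the x axes differ in range. H2-K1 stood at 0.82 in proliferating cancer cells, where 7 genes passed.

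Vcan+ monocytes of BD+ICB tumours had 13 raised genes and 0 lowered over ICB by edgeR, out of 658 at an unadjusted p under 0.05, while DESeq2 called 18 in all. B2m rose from 3040 ± 61.8 to 4443 ± 302 CPM (SD, n = 3; log2 fold 0.55 ± 0.08, edgeR adjusted p = 0.00455), and Cd274, which encodes the PD-1 ligand PD-L1, from 229 ± 27.3 to 401 ± 18.0 (0.80 ± 0.14, adjusted p = 0.0255). Nampt, an enzyme of NAD synthesis, rose by 1.07 ± 0.15 (adjusted p = 0.00455), and Tapbp, Isg15, Oasl1 and Ifi205 rose by 0.72 to 1.88. All 17 interferon-gamma response genes had positive folds (median 0.70, camera adjusted p = 1.2e-15, adjusted p = 0.153 with an estimated correlation), 1 past adjustment over all genes and 7 adjusted over the list alone. The MHC class I list had 2 genes raised over all and 10 adjusted over the list alone (median 0.33, camera adjusted p = 1.5e-07, adjusted p = 0.153 with an estimated correlation). The dissociation and immediate early list was called higher in the same cells, with a mean of 0.11 and a median of -0.0092 over 19 genes, 0 past adjustment over all genes and 5 higher adjusted over the list alone (camera adjusted p = 0.048, adjusted p = 0.248 with an estimated correlation). The count fell to 0 without ICB replicate 2 or without BD+ICB replicate 1, to 1 without BD+ICB replicate 2 and to 7 without ICB replicate 1, and was 37 without ICB replicate 3. The calls for B2m, Cd274 and Nampt ended without ICB replicate 2 (adjusted p = 0.0666, 0.111 and 0.0666) or BD+ICB replicate 1 (0.0931, 0.131 and 0.0749). B2m and Cd274 also lost theirs without BD+ICB replicate 2 (0.0537 and 0.0692), and that for Cd274 without BD+ICB replicate 3 (0.0529).

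In Cxcr2+ neutrophils, 3 genes rose, namely Bcl2a1b (1.58 ± 0.29, edgeR adjusted p = 0.0133), a survival factor of the Bcl2 family, Ifi47 (1.57 ± 0.32, adjusted p = 0.0251), an interferon-induced GTPase, and Il1rn (1.22 ± 0.26, adjusted p = 0.0344), the interleukin-1 receptor antagonist. Igfbp6 fell (-3.43 ± 0.55, edgeR adjusted p = 0.00149). All 16 tested MHC class I genes had positive folds (median 0.81), with 0 past adjustment over all genes and 9 adjusted over the list alone. That list (camera adjusted p = 4.1e-14) and the chemokines and receptors list (median 0.69 over 13 genes, camera adjusted p = 6.4e-04, 0 over all genes and 3 adjusted over the list alone) were the 2 list calls of this comparison kept with an estimated correlation, both at an adjusted p of 0.0476. Glycolysis genes were lower in these cells (median -0.44 over 17 genes, 0 past adjustment over all genes and 3 lower adjusted over the list alone, camera adjusted p = 2.8e-04, adjusted p = 0.173 with an estimated correlation). The calls for Bcl2a1b, Ifi47 and Il1rn ended with own demultiplexing (adjusted p = 0.161, 0.529 and 0.541), without ICB replicate 2 (0.147, 0.25 and 0.25) or without BD+ICB replicate 2 (0.15, 0.156 and 0.277). Bcl2a1b and Il1rn also lost theirs without ICB replicate 1 (0.0817 and 0.203) or BD+ICB replicate 1 (0.063 and 0.0898). The call for Il1rn further ended without SD replicate 3 (0.062), and those for Ifi47 and Igfbp6 without BD+ICB replicate 3 (0.0687 and 0.0927). The number of genes was 15 without ICB replicate 3, 7 without SD replicate 2, 2 without ICB replicate 1, and 1 without ICB replicate 2 or BD+ICB replicate 2.

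In CD8 T cells of BD+ICB tumours, 5 genes rose and 42 fell relative to ICB. Gzmb (ENSMUSG00000015437), the cytotoxic protease granzyme B, rose from 579 ± 172 to 1284 ± 183 CPM (SD, n = 3; log2 fold 1.13 ± 0.22, edgeR adjusted p = 0.0231). The chemokine receptor Cxcr6 rose by 0.71 ± 0.17 (adjusted p = 0.0367). Klra1, a killer lectin-like receptor, had no count in the ICB tumours and 27.7 ± 11.3 CPM in BD+ICB (edgeR adjusted p = 0.00308), at least 13.5-fold higher than a floor of 3 counts over the ICB group. Ifng had a fold of 1.15 ± 0.29 and did not pass (adjusted p = 0.144), and the checkpoint genes Pdcd1 (0.21 ± 0.42, adjusted p = 0.953) and Ctla4 (0.072 ± 0.19, adjusted p = 0.979) did not either. Klf2, a transcription factor of naive T cells, fell (-1.34 ± 0.28, edgeR adjusted p = 0.0248), as did Tox, a regulator of T-cell exhaustion (-1.89 ± 0.39, adjusted p = 0.0129). Of the cytotoxic effector list, 15 genes were tested, 1 rose and 1 fell over all genes, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0619). The call for Klra1 ended without BD+ICB replicate 2 (adjusted p = 0.0634). Cxcr6 lost its call without any 1 of the ICB and BD+ICB tumours (0.0533 to 0.305). Tox lost it without ICB replicate 1 (0.255), ICB replicate 3 (0.0528), BD+ICB replicate 1 (0.0723) or BD+ICB replicate 2 (0.205). Klf2 lost it without SD replicate 1 (0.0585), SD replicate 3 (0.0559), ICB replicate 2 (0.159), ICB replicate 3 (0.128) or BD+ICB replicate 1 (0.0891).

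The lowered genes with the smallest adjusted p in the CD8 T cells were transcripts abundant in neutrophils and other myeloid cells, such as Clec4e (-3.73 ± 0.35, edgeR adjusted p = 8.1e-07), Hcar2 (-4.33 ± 0.53, adjusted p = 3.5e-05), Nlrp3 (-3.16 ± 0.37) and Il1rn (-2.43 ± 0.30). Over 9 neutrophil markers tested in these cells, the median fold was -4.71. The suppressive granulocyte list had 3 of 13 genes lower over all genes and 9 adjusted over the list alone (median -2.02, camera adjusted p = 1.8e-08, adjusted p = 0.0861 with an estimated correlation). In cells whose top hashtag was at least 3 times the second, 3 genes passed instead of 47, with Gzmb (1.20, adjusted p = 0.0265) and Klra1 among them. Under this rule, Cxcr6 (0.68), Klf2 (-0.83), Tox (-2.01), Clec4e (-1.51), Hcar2 (-2.31), Nlrp3 (-1.76) and Il1rn (-0.74) lost their calls, and the median fold was -4.39 over the 5 neutrophil markers still tested. With own demultiplexing 8 passed. The count was 78 without ICB replicate 1, 28 without ICB replicate 2 or BD+ICB replicate 1, 21 without ICB replicate 3 and 16 without BD+ICB replicate 2. The call for Gzmb ended without ICB replicate 2 (0.98, adjusted p = 0.0736), ICB replicate 3 (adjusted p = 0.171), BD+ICB replicate 2 (adjusted p = 0.114) or BD+ICB replicate 3 (adjusted p = 0.0564).

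In the class named CD4 T cells, 7 genes rose and 14 fell. The class had 12 of 12 T cell markers over 20 CPM (median 461) and 3 of 8 mast cell or basophil markers (median 11.2), and the mast cell protease gene Mcpt2 was among its 10 leading genes. Il2ra, the high-affinity interleukin-2 receptor chain, rose by 2.01 ± 0.43 (edgeR adjusted p = 0.0477) and Tmsb4x, an actin-binding peptide, by 0.46 ± 0.08 (adjusted p = 0.00745). Slpi (-3.98 ± 0.49, edgeR adjusted p = 3.2e-04), Il1rn (-2.48 ± 0.33) and Ccl3 (-2.88 ± 0.43, adjusted p = 0.00506) fell. Slpi and Il1rn are transcripts abundant in myeloid cells. Their calls and that for Ccl3 were not among those that ended with the stricter hashtag rule or own demultiplexing. The NF-kB and TNF early response list had 3 of 15 genes lower over all genes and 5 adjusted over the list alone (camera adjusted p = 9.9e-07, adjusted p = 0.175 with an estimated correlation). The count of 21 fell to 4 without ICB replicate 1 or without BD+ICB replicate 2. The call for Il2ra ended without ICB replicate 1 (adjusted p = 0.373), ICB replicate 3 (0.0979), BD+ICB replicate 1 (0.146) or BD+ICB replicate 2 (0.243). Ccl3 lost its call without ICB replicate 1 (0.0642) or BD+ICB replicate 2 (0.0585), and that for Slpi without ICB replicate 1 (0.0588). In NK cells, with 2 ICB and 2 BD+ICB tumours in the fit, 1 gene rose and 5 fell, among them Ier3 (-1.85 ± 0.46, edgeR adjusted p = 0.0236), whose call ended without ICB replicate 1 (-1.01, adjusted p = 0.864), BD+ICB replicate 1 (0.507) or BD+ICB replicate 2 (0.0768), each leaving an arm of 1 tumour, assumed to vary like the other groups. The dissociation and immediate early list, which does not hold Ier3, was lower in the same cells, with 12 of 15 folds negative, 0 genes over all and 3 lower adjusted over the list alone (median -0.37, camera adjusted p = 0.00483, adjusted p = 0.368 with an estimated correlation). The number of genes in NK cells was 0 without ICB replicate 1, 12 without BD+ICB replicate 2, 14 without ICB replicate 3 and 15 without SD replicate 1 or SD replicate 2.

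Macrophages differed in few genes under blockade. The fractalkine receptor Cx3cr1 (ENSMUSG00000052336) fell from 132 ± 35.1 (n = 3) to 11.2 ± 5.50 (n = 2) CPM in the class of other macrophages (log2 fold -3.49 ± 0.42, edgeR adjusted p = 2.9e-05) and fell in M1 macrophages (-3.46 ± 0.42, adjusted p = 0.0128). Pdcd1lg2, which encodes the PD-1 ligand PD-L2, rose in M1 macrophages from 2.84 ± 1.28 to 24.1 ± 10.8 CPM (SD, n = 3; 3.06 ± 0.55, adjusted p = 0.0179), as did the integrin Itga1 (1.85 ± 0.29), whereas Apoc2 fell (-1.17 ± 0.20). S100a8, an abundant neutrophil transcript, fell in Mmp+ M2 macrophages (-2.02 ± 0.30, edgeR adjusted p = 0.00922) and lost its call with the stricter hashtag rule (-1.03) and without BD+ICB replicate 1 (adjusted p = 0.0634) or BD+ICB replicate 2 (0.0552). In M1 macrophages, calls ended without ICB replicate 1 for Cx3cr1 (adjusted p = 0.103), Pdcd1lg2 (0.242) and Itga1 (0.103), and without ICB replicate 2 for Pdcd1lg2 (0.0865), Itga1 (0.0602) and Apoc2 (0.0865). They ended without ICB replicate 3 for Pdcd1lg2 (0.0637) and Apoc2 (0.0637), without BD+ICB replicate 1 for Cx3cr1 (0.152) and Apoc2 (0.289), and without BD+ICB replicate 2 for Cx3cr1 (0.133), Itga1 (0.133) and Apoc2 (0.198). Nos2, the inducible nitric oxide synthase, had folds of 1.87 ± 0.42 in M1 (adjusted p = 0.324) and 3.09 ± 0.60 in Trem2+ macrophages (adjusted p = 0.116). The interferon-gamma response list was higher in Mmp+ macrophages, with 14 of 14 folds positive, 0 genes over all and 3 adjusted over the list alone (camera adjusted p = 4.5e-14, adjusted p = 0.0815 with an estimated correlation). Trem2+ macrophages gave 0 genes with edgeR (308 at an unadjusted p under 0.05, 1 with DESeq2), Nos2+ dendritic cells 0 (296 and 3) and proliferating immune cells, a mixed class of macrophages and T cells, 0 (515 and 13).

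Whether the diet effect itself differed between mice with and without blockade was tested in 4 classes. Hcar2 in Cxcr2+ neutrophils was the 1 gene that passed, with a log2 interaction of 2.57 ± 0.44 (edgeR adjusted p = 0.00434). Its level was 973 ± 165 CPM in SD (n = 3), 249 ± 128 in BD (n = 2), 1602 ± 165 in ICB and 2561 ± 160 in BD+ICB (SD, n = 3). The BD arm held 15 and 12 Cxcr2+ neutrophils, in BD replicates 2 and 3. Hcar2 was also among the 10 leading genes of Hilpda+ neutrophils. In that class, with 1 BD and 1 BD+ICB tumour in the fit, the diet effect could not be tested. M1 macrophages gave 0 genes with edgeR (467 at an unadjusted p under 0.05, 4 with DESeq2), Mmp+ macrophages 0 (233 and 1) and Trem2+ macrophages 0 (239 and 0). The MHC class I list had positive interactions in all 4 classes, with medians of 0.63 in M1, 0.56 in Mmp+ and 0.41 in Trem2+ macrophages and 1.16 in Cxcr2+ neutrophils. In M1 macrophages camera called this list lower in BD than SD tumours, which enters the interaction. That lower direction turned without SD replicate 1. Over all genes 0 members passed in each class, and adjusted over the list alone 3 passed in M1 macrophages and 4 in Cxcr2+ neutrophils. The camera adjusted p ranged from 1.2e-07 in M1 to 5.8e-04 in Trem2+ macrophages, and with an estimated correlation the adjusted p was 0.306, 0.398, 0.796 and 0.315 in the order given. The call for Hcar2 ended without BD replicate 3 (2.22, adjusted p = 0.115), which left 1 BD tumour, assumed to vary like the other groups, and with own demultiplexing (0.70, adjusted p = 0.965). The number of genes was 10 without SD replicate 3 or BD replicate 1, 3 without ICB replicate 1, 2 without SD replicate 1, BD replicate 2 or BD+ICB replicate 3, and 7 with DESeq2.

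Averaged over both libraries, the diet effect gave 6 genes in the 4 classes tested. In M1 macrophages, Ptgs2 (1.38 ± 0.18, edgeR adjusted p = 0.0109) and Slc7a11, the cystine transporter (0.70 ± 0.12, adjusted p = 0.0184), rose, and Cd300c2 fell (-0.77 ± 0.13, adjusted p = 0.0127). In Mmp+ macrophages, Fabp5 rose (0.96 ± 0.15) and S100a8 fell (-1.67 ± 0.23, both adjusted p = 0.00286), but with the stricter hashtag rule S100a8 stood at -0.56 (adjusted p = 0.857) and Fabp5 at 0.83 (adjusted p = 0.154). Igfbp6 fell in Cxcr2+ neutrophils (-1.80 ± 0.35, adjusted p = 0.0356), a call that ended with DESeq2 (adjusted p = 0.051), RLE size factors (0.0706), the stricter hashtag rule (0.285) and without any 1 tumour of its fit other than SD replicate 2, BD replicate 3 and ICB replicate 3 (highest adjusted p = 0.232). The call for Slc7a11 ended without SD replicate 1 (0.0828), BD replicate 1 (0.19), ICB replicate 1 (0.0707), ICB replicate 2 (0.0666), BD+ICB replicate 1 (0.0987) or BD+ICB replicate 2 (0.101). In M1 macrophages the runs without SD replicate 1 or 3 or BD replicate 1 or 3, and in Cxcr2+ neutrophils those without BD replicate 2 or 3, left an arm of 1 tumour, assumed to vary like the other groups. Ptgs2 lost its call with the replicate block and without ICB replicate 2 (0.0861). Cd300c2 lost its call without ICB replicate 2 (0.0666) or BD+ICB replicate 1 (0.0974). Trem2+ macrophages gave 0 genes with edgeR, 363 at an unadjusted p under 0.05 and 1 with DESeq2. The NF-kB and TNF early response list was higher in Cxcr2+ neutrophils, with 18 of 19 folds positive, 0 genes over all and 4 adjusted over the list alone (median 0.39, camera adjusted p = 2.5e-14, adjusted p = 0.109 with an estimated correlation). For the genes raised by deacetylase inhibitors and for the histone deacetylases, which the title of the series brings up, camera called 0 of 25 and 0 of 19 tests over all diet comparisons (smallest adjusted p = 0.224 and 0.191). The number of genes was 19 without ICB replicate 3, 17 without BD replicate 3, 14 without SD replicate 3 or ICB replicate 1, 12 without BD replicate 1, and 31 with DESeq2.

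Differences between tumours with and without blockade are given as a description, because the blockade and the library could not be told apart. Merged T cells made up 3.55% ± 0.0847 of SD and 12.5% ± 5.18 of ICB cells, and 3.86% ± 3.28 of BD and 22.7% ± 10.3 of BD+ICB cells (SD, n = 3; both exact permutation p = 0.1, the smallest possible). H2-K1 in proliferating cancer cells stood at 285 ± 9.49 CPM in SD (n = 2) and 807 ± 48.6 in ICB tumours (SD, n = 3). Over 12 classes, edgeR called 1504 genes between ICB and SD, 633 higher and 871 lower, and over 4 classes 445 between BD+ICB and BD, 280 higher and 165 lower. Trem2+ macrophages accounted for 289 and 199 of these.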

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

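The tests of the hashtag limit, of how S100a8 and S100a9 spread over cells, and of other groupings of the tumours were chosen only after the results were seen.

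Hcar2 in Cxcr2+ neutrophils drew attention because the diet effect differed between libraries in a test of the difference itself (log2 interaction 2.57, edgeR adjusted p = 0.00434). Signals outside the comparisons were tdTomato, with 58 UMIs in mesenchymal cells (16.2% of cells) and 113 in proliferating cancer cells (47.1%), and EGFP, with 33 (8.30%) and 57 (27.9%) UMIs in these classes. Other classes held 0 to 2 UMIs of either, at lower median depths (2393 UMIs per cell in Cxcr2+ neutrophils, 21890 in mesenchymal and 108600 in proliferating cancer cells). Own demultiplexing assigned 3716 more cells than were deposited, a net number. It left out deposited cells that failed its rule of a top hashtag 3 times the second, which 5325 of 5749 passed.

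The limit of 500 hashtag counts may account for part of the lower neutrophil share in BD than SD tumours, but how much cannot be told. Own demultiplexing also required the top hashtag to be 3 times the second, so its differences are not those of lifting the limit alone. In that setting the difference was 7.35 points over all cells (-15.6 deposited) and -4.89 over immune cells (-21.7 deposited). Over immune cells without BD replicate 2, it was still -19.2 against -31.9, over the bound of 0.5 times the deposited value set for this explanation, but it stayed within that bound without each other tumour: 3.27 against -13.8 (BD replicate 1), 1.28 against -19.5 (BD replicate 3), -10.7 against -27.7, -3.34 against -19.1 and -0.679 against -18.3 (SD replicates 1, 2 and 3). Between BD+ICB and ICB the difference was still -18.3 points against -26.05 deposited, with too few tumours to tell (exact permutation p = 0.2). Over immune cells it was -22.7 against -27.9. With every tumour and without each, 0.618 to 0.842 times the deposited difference remained, over the bound of 0.5 in every run. A link to tumour size cannot be told apart from diet: within groups, log size and neutrophil share gave Pearson r = -0.167 (permutation p = 0.707) and a rank correlation of -0.203 (permutation p = 0.601), and r = -0.172 (permutation p = 0.889) without BD+ICB replicate 2 and SD replicate 1. An effect of the diet itself stays open.

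For the lower neutrophil transcripts in CD8 T cells of BD+ICB tumours, the values argue against free RNA in all droplets, since 96.8% of S100a8 and S100a9 UMIs in ICB tumours lay in 11 of 215 cells and 80.0% of cells had none. The test fixed beforehand had come out in favour of free RNA, with a median fold of -4.39 over 5 markers under the stricter hashtag rule against -4.71 over 9. In cells passing that rule, S100a8 and S100a9 stood at 18.9 per 10000 UMIs in ICB replicate 2, at 0.184 and 0.477 in ICB replicates 1 and 3 and at 0.179 to 0.357 in BD+ICB, so that for these genes 1 tumour carried the remaining difference. Droplets holding a T cell and a neutrophil may be a source but cannot be told apart: cells failing the stricter rule held 120 and 138 times the level of passing cells in ICB replicates 1 and 3, but 0.249 times in ICB replicate 2. Neutrophil transcripts made by T cells were not tested.

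For the higher MHC class I genes in proliferating cancer cells of BD+ICB tumours (median 0.81), the values argue against admixed immune RNA, since the highest median fold of 4 immune marker lists was -0.51 (monocytes; the T cell list rested on 1 gene). A response of the cancer cells to diet under blockade may account for it, as a hypothesis found and tested on the same tumours. Tumour size, tied to diet, stays open.

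Within a library, the groupings of the same tumours were too few, at 10 with the real one included, to give a share under 0.05. For BD against SD the real count and the highest other were 1 and 2 in Mmp+ and 0 and 4 in Trem2+ macrophages, with 3 and 10 groupings as large, the real one included. For BD+ICB against ICB they were 47 and 2 in CD8 T cells, 21 and 4 in CD4 T cells, 13 and 1 in Vcan+ monocytes, 4 and 1 in M1 macrophages and in Cxcr2+ neutrophils, and 1 and 0 in Mmp+ macrophages, with 1 grouping as large in each, the real one itself, and 0 and 0 in Trem2+ macrophages and proliferating immune cells, with 10. Over both libraries, 1 of 40 groupings, the real one itself, gave as many genes as the 2 of the diet effect in Mmp+ macrophages, where the highest other was 1. This share was under 0.05, but it is the smallest that 40 groupings can give. It was not adjusted for the other counts tested in the same way, so chance stays open for this count. The margin was 1 gene, and both genes lost their calls with the stricter hashtag rule (Fabp5 adjusted p = 0.154, S100a8 0.857). With a real count of 0, all 40 groupings are as large by construction, so nothing can be told for the diet effect in Trem2+ macrophages (highest other 3) or the interaction in Mmp+ (1) and Trem2+ macrophages (2). The same holds for the counts of 0 within a library.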

How the results depend on the processing

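The tests of merged compartments and of own demultiplexing among immune classes or without single tumours were chosen only after the class results were seen. Among 81 calls of named genes, own demultiplexing kept 28, ended 43 and turned the direction of 3. The stricter hashtag rule kept 44, ended 29 and turned 1. DESeq2 ended 14 and kept 64, and only the tumours of the library ended 12 and kept 59. The replicate block ended 9 and RLE size factors 5. A least number of 30 cells per tumour kept 29 and ended 5. Calls neither kept, ended nor turned had no adjusted p in that setting. Leaving out a tumour ended 45 (BD+ICB replicate 1 or 2), 43 (ICB replicate 2), 41 (ICB replicate 1), 27 (ICB replicate 3), 18 (BD+ICB replicate 3) and 2 to 10 (each SD or BD tumour), whereas cells with at least 1000 UMIs and the deposited expression table ended 0. The cause of the changes below was not tested. Depth was lowest in BD replicate 2, with 70 cells and 510992 UMIs. Over single genes, lists and classes, 8641 values stayed on their side of the threshold, 787 lost a call, 307 gained one and 8 turned with a call on at least 1 side. Another 269 moved, namely 195 counts of genes, by over 1.5 times, and 74 values that turned with no call on either side.

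For class shares, edgeR on cells gave 5 calls for BD minus SD, 2 for BD+ICB minus ICB (-3.36 for Hilpda+ neutrophils, 2.26 for Nos2+ dendritic cells) and 7 for the diet effect, with log2 folds of 2.08 for Nos2+ dendritic cells, 1.71 for M1 macrophages, -2.12 for mesenchymal cells, -1.26 for Cxcr2+, -1.97 for Hilpda+ and -3.54 for Ifit+ neutrophils and -1.95 for proliferating cancer cells. The diet effect gave 2 calls without neutrophils (mesenchymal -10.3 and proliferating cancer cells -3.86 points), 2 with the stricter rule (mesenchymal -6.14, Ifit+ neutrophils -1.41), and 0 to 2 over left-out tumours (M1 macrophages 7.48 to 10.8, mesenchymal -6.55 to -5.70, proliferating cancer cells -2.52 to -1.91).

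For merged compartments, edgeR gave log2 folds of -1.43 for neutrophils and 1.46 for dendritic cells. Left-out tumours gave -26.5 to -17.0 points for neutrophils, 12.1 to 17.1 for macrophages, 2.35 to 7.27 for T cells, 5.40 to 8.45 for dendritic cells, -6.55 to -5.70 for mesenchymal, -2.52 to -1.91 for proliferating cancer and -0.140 to 1.45 for proliferating immune cells. Own demultiplexing gave 1.21 for NK, -15.9 for mesenchymal and -2.27 for proliferating cancer cells, and among immune classes -0.643 for macrophages, 0.762 for NK and -0.535 for proliferating immune cells, which stood at -0.226 without neutrophils. The stricter rule gave -2.15 for proliferating cancer cells.

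Counts of genes moved as follows. With at least 30 cells per tumour, smaller classes such as proliferating cancer cells were no longer tested. The counts of that setting therefore do not show that their calls failed. For BD against SD: DESeq2 31, no filter 71, at least 30 cells 0, only the library 2, left-out tumours 2 to 23. For BD+ICB against ICB: no filter 1067, at least 30 cells 75, left-out tumours 108 to 352. In Vcan+ monocytes: no filter 133, stricter rule 21, left-out tumours 0 to 37. In proliferating cancer cells: no filter 413, stricter rule 64, own demultiplexing 156, left-out tumours 35 to 116. In CD4 T cells: no filter 71, own demultiplexing 12, left-out tumours 4 to 29. In CD8 T cells: no filter 126, stricter rule 3, own demultiplexing 8, left-out tumours 16 to 78. For the interaction: DESeq2 7, no filter 28, stricter rule 3, left-out tumours 0 to 10. For the diet effect: DESeq2 31, no filter 132, left-out tumours 4 to 19.

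Whether same-numbered tumours shared more than a number cannot be told. Their deviations correlated at -0.0167 to 0.194 over 12 values from 2 macrophage classes, not all above 0.1. Only ICB and BD+ICB replicates 2 in Mmp+ macrophages gave a negative value. With the replicate block, genes numbered 523 for BD+ICB against ICB, 156 in Vcan+ monocytes, 182 in proliferating cancer and 78 in CD8 T cells, 2 for the interaction and 14 for the diet effect.

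List calls numbered 0 with an estimated correlation and 0 with fry for BD against SD, the interaction and the diet effect, and 2 and 9 for BD+ICB against ICB. Over left-out tumours they numbered 8 to 23 for BD against SD and 9 to 25 for the interaction.

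Directions of called values turned for Hcar2 in neutrophils, BD against SD (0.055 with own demultiplexing), and in CD8 T cells for Basp1 (0.67) and Ccl3 (2.49) with own demultiplexing and for Tnf with the stricter rule (0.82) and own demultiplexing (0.96). In M1 macrophages, MHC class I, BD against SD, turned without SD replicate 1 (adjusted p = 0.656, left-out range 1.6e-09 to 0.77), as did the interferon-gamma interaction (0.368, range 1.6e-12 to 0.681). Type I interferon for the diet effect in neutrophils turned without BD replicate 2 (range 0.00232 to 0.996).

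Of the uncalled values that turned, 9 did so with own demultiplexing and 10 among its immune classes. For BD minus SD, own demultiplexing moved Cxcr2+ neutrophils from -11.6 to 3.93 points, Hilpda+ neutrophils from -2.83 to 3.46, CD8 T cells from -1.33 to 0.859 and NK cells from -1.89 to 0.524, besides merged neutrophils from -15.6 to 7.35. Among its immune classes, Cxcr2+ and Hilpda+ neutrophils stood at -4.47 and -0.0071 and NK cells at -0.440, CD8 T cells at 0.178, and Trem2+ macrophages at -5.97 against 6.58 over all deposited cells. The diet effect on NK cells went from -0.875 to 1.21, and the interaction for Cxcr2+ neutrophils from 1.14 to -11.5.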

Other observations

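No test in this part was chosen after the result was seen, apart from the choice of which list results to describe and the makeup of the proliferating immune cells.

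The class of proliferating immune cells was a mix of macrophages and T cells, and the mix was not compared between groups by a test. By own clusters, T cells made up 16.7% to 33.3% of the class in ICB and 25% to 90% in BD+ICB tumours, with overlap. Own clusters placed 24.1% ± 8.49 of its cells in ICB and 57.4% ± 32.5 in BD+ICB tumours among T cells (SD, n = 3), and in the summed counts of BD+ICB over ICB 12 of 12 T cell markers had positive folds (median 1.75) and 12 of 12 macrophage markers negative ones (median -1.24). The list values of this class therefore do not separate a change within cells from a change of the mix. It had 12 of 13 cytotoxic effector genes with positive folds over ICB (median 1.81, camera adjusted p = 6.9e-08, adjusted p = 0.526 with an estimated correlation), 0 past adjustment over all genes and 6 adjusted over the list alone. All 9 MHC class II genes had negative folds there (median -0.92, camera adjusted p = 3.1e-06, adjusted p = 0.526 with an estimated correlation), with 0 past either adjustment. In Vcan+ monocytes all 6 tested genes of the immature neutrophil granule list had negative folds (median -0.73, camera adjusted p = 2.4e-05, adjusted p = 0.153 with an estimated correlation), with 0 genes over all and 1 lower adjusted over the list alone. Of the 8 tested prostate epithelium genes in proliferating cancer cells, 2 had positive folds, and camera called the list lower (median -0.58, camera adjusted p = 0.0381, adjusted p = 0.286 with an estimated correlation), with 0 past either adjustment.

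Trem2+ macrophages of BD over SD tumours had a higher hypoxia list (median 0.32) and a lower oxidative phosphorylation list (median -0.21), both at a camera adjusted p of 0.00566 (adjusted p = 0.433 and 0.718 with an estimated correlation), with 0 genes past either adjustment. For Cxcr2+ neutrophils and the diet effect, the type I interferon list was called higher by camera (adjusted p = 0.0328, adjusted p = 0.341 with an estimated correlation) with a median of 0.22 and a mean of -0.064. The chemokine list was called higher (adjusted p = 0.0276, adjusted p = 0.109 with an estimated correlation) with a median of -0.19 and a mean of 0.090. In both, median and mean differed in sign, and 0 genes passed over all genes, with 0 and 2 adjusted over the list alone.

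Over the 4 diet comparisons, camera called MHC class I in 14 of 25 tests, MHC class II in 11 of 25, type I interferon in 11 of 23, interferon-gamma in 10 of 25, glycolysis in 9 of 25. Of these calls 13, 5, 6, 9 and 5 were higher with the diet or, for the interaction, positive, and the others lower. It called the classically activated macrophage list in 8 of 23, NF-kB in 7 of 25, chemokines, dissociation and inflammasome in 6 of 25 each, hypoxia in 5 of 25. It called exhaustion in 3 of 21, fatty acid oxidation in 3 of 19, alternatively activated macrophage in 3 of 18, suppressive granulocyte in 2 of 24 and oxidative phosphorylation in 2 of 25. It called 1 test each of cytotoxic effectors (of 8), fibroblast genes (of 23), ketone body use (of 19), naive and memory T cells (of 18), immature neutrophil granules (of 5), prostate epithelium (of 1) and regulatory T cells (of 3). With an estimated correlation, 1 MHC class I and 1 chemokine call remained and 0 of every other list. With the preset correlation, camera called 0 of 9 for proliferation (smallest adjusted p = 0.0527), and the red cell list had too few genes to be tested.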
